A study of Mus musculus with 5 samples.

How the data were processed

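Poly-A RNA from MG5 cells was sequenced as TruSeq stranded libraries in 3 groups: 10 µM 6OHA for 6 h (1 library, replicate 2), 10 µM bexarotene (BEX) for 6 h (3 libraries, replicates 1 to 3) and untreated (1 library, replicate 3). The study describes 3 samples per group, and the remaining 6OHA and untreated samples were not analysed here. The authors deposited 1 gene table for mm10 with read counts, FPKM and TPM for these 5 libraries. Counts were whole numbers and were used for every test, deposited TPM were used only in alternative tests, and deposited FPKM were not used in any test. The submitters' notes name bcl2fastq 2.20.0, Trimmomatic 0.38, Bowtie2, HISAT2 2.1.0, SAMtools 1.9 and StringTie 2.1.3b. The role of each tool and the use of strand in counting were not given in the sources used here. The table held 45777 genes, of which 45679 were matched by gene identifier to RefSeq GRCm38.p6 for positions and overlaps with neighbours. GC content and length were available for 35547 genes, including 14387 of the 15462 tested genes (93%).

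Libraries held 34738597 (6OHA), 33823181, 36169845 and 40545305 (BEX 1 to 3) and 35441084 (untreated) counts, with 18273 to 18550 genes above 0. TMM factors lay between 0.9942 and 1.004. A count of 0 was given a ceiling of 3 counts per library, and a fold against a group at 0 was computed against that ceiling. These ceilings cover counting error only, since reads amplified by PCR are not independent molecules.

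All 5 libraries entered a single edgeR quasi-likelihood fit (glmQLFit and glmQLFTest in edgeR 4.0.16, R 4.3.3) with 3 groups and TMM factors. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which equals 0.282 CPM at its count minimum. The spread came from the 3 BEX libraries, with 2 residual degrees of freedom, 10.6 prior degrees of freedom and a common dispersion of 0.00287. The lone 6OHA and untreated libraries were assumed to vary like the BEX libraries. The 3 contrasts were BEX vs untreated, 6OHA vs untreated and 6OHA vs BEX, each two-sided with Benjamini-Hochberg adjustment at 0.05. Standard errors and 95% intervals of fold changes came from the same fit and include the spread between BEX libraries. They were computed from fitted means and dispersions rather than from the F test, so an interval and a p-value need not match. The median SE of the log2 fold change was 0.112, 0.137 and 0.114 in these contrasts.

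The 22 gene lists were written from general knowledge of these pathways and cell types: LXR targets, fatty acid and triglyceride synthesis, PPAR targets, RAR targets, RXR and its partners, cholesterol synthesis and uptake, inflammatory cytokines and the NF-kB response, interferon-stimulated genes, homeostatic and disease-associated microglia, alternative macrophage activation, amyloid handling, efferocytosis, the unfolded protein and integrated stress response, NRF2 targets, cell cycle, immediate-early genes, mitochondrially encoded genes, and astrocyte, neuron, oligodendrocyte and fibroblast and endothelial markers. Lists with at least 5 tested genes (20 of 22; astrocytes had 3 and neurons 4) were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01. The test was repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance 1 way without reference to other genes. With an estimated correlation 0 lists passed in any contrast, and a list with a true shift in simulated data had an adjusted p = 0.198 by that method against 3.29e-25 with the preset value. Genes were drawn independently in that simulation, so it does not show whether the preset value suits lists whose genes move together. Fry passed 7, 6 and 0 lists in the 3 contrasts.

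Named genes followed a rule: per contrast, the 10 largest rises and 10 largest falls among called genes with a mean of at least 20 counts and all 3 BEX libraries on the same side where BEX is compared, leaving out numbered Gm and Rik symbols; 27 anchor genes whatever their p, where tested; and up to 4 called members with the smallest adjusted p per list. The contrasts, tests, lists, anchor genes, naming rule and the alternatives listed next were fixed before the data were examined. These alternatives were RLE factors, DESeq2 1.42.0, limma-voom, the older edgeR quasi-likelihood method, limma-trend on log2(TPM + 1) and on log2(TPM + 0.1), no filter, a minimum mean of 20 counts, an absolute log2 fold change of at least 1, leaving out each BEX library, and a fit of only the compared groups. Chosen after seeing the data were offsets per library from a spline of log2 CPM deviations on GC content and length, a restriction to genes above 0 in every library, and limma-voom for single genes.

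The pipeline was tested on simulated data with known folds over 15454 genes. At true folds of 1.5, 2 and 4 it called 67.7%, 92.5% and 98.5% of changed genes in BEX vs untreated, 65.7%, 80.3% and 90.3% in 6OHA vs untreated, and 73.1%, 91.3% and 95.6% in 6OHA vs BEX. Unchanged genes made up 9.13%, 9.71% and 6.96% of calls, 95% intervals covered the truth for 97%, 97.4% and 97% of genes, and 0 of 20 random lists were called. The simulation draws every group with the same spread, so it does not test the assumption made for the lone libraries. It also draws genes independently, so it does not test the preset correlation. Shared response to both agonists was measured against 40 sets simulated with no change and the same single control. Pairs of BEX libraries had a chi-square per degree of freedom of 4.44 to 5.7, against 15.1 to 18.4 for 6OHA with BEX and 35.3 to 40.2 for treated with untreated. Dixon's test for a stray library was not applied, since the groups held 1 or 3 libraries.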

Results

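MG5 is a mouse microglial cell line, grown here in medium conditioned by A1 astrocyte-like cells. Cells were left untreated or received 10 µM bexarotene (BEX) or 10 µM 6OHA for 6 h. BEX is a drug that activates the retinoid X receptor (RXR), a nuclear receptor that pairs with the liver X receptors (LXR), the PPARs and the retinoic acid receptors (RAR). 6OHA is the code name of a second RXR agonist, and the question was how the response to it differed from the response to BEX. The values below came from 5 poly-A RNA-seq libraries: 3 BEX libraries, 1 6OHA library and 1 untreated library. The study describes 3 samples per group, and the other 6OHA and untreated samples were not analysed here. Spread was therefore estimated from the 3 BEX libraries alone, and the lone 6OHA and untreated libraries were assumed to vary like them. Nothing in the descriptions says that replicates were separate cultures, so the p-values measure only the spread between these samples. The sample labels used here give no time point or vehicle for the untreated library. Effects of a vehicle or of handling therefore cannot be told apart from effects of the agonists in comparisons with it.

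A gene was called when its adjusted p, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15462 tested genes, was under 0.05. Levels are in CPM (counts scaled to a common library size), BEX levels are means ± SD (n = 3), and log2 fold changes carry the standard error (SE) of the fit. Libraries held 33823181 to 40545305 counts, so a count of 0 allowed a level of up to 0.0743 to 0.0885 CPM for counting error alone. Positions refer to RefSeq GRCm38.p6, the assembly that mm10 names, and values are sums over whole genes.

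BEX raised Plin2, Abca1, Tgm2 and Arg1 within 6 h. Plin2, which coats lipid droplets (Entrez gene 11520, chromosome 4, 86626910 to 86670217), stood at 429 CPM in untreated cells and 1570 ± 7.14 CPM with BEX, a log2 fold change of 1.87 ± 0.043 (SE, adjusted p = 1.46e-11). Abca1, the LXR-driven cholesterol exporter (Entrez gene 11303, chromosome 4, 53030789 to 53159988), went from 400 to 793 ± 24.1 CPM, a 1.99-fold rise (adjusted p = 1.49e-08). Tgm2, a transglutaminase gene under RAR control, rose 3.69-fold from 284 to 1050 ± 27.3 CPM (adjusted p = 3.24e-11). Arg1, the arginase of alternatively activated macrophages (Entrez gene 11846, chromosome 10, 24915207 to 24927470), rose 27.9-fold from 2.78 to 77.7 ± 5.83 CPM (adjusted p = 4.97e-10). Across all tested genes, 1168 were called higher and 933 lower (55.6% higher, against 67.7% with limma on log2(TPM + 1)), and 201 of the 2101 changed at least 2-fold.

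Alternative macrophage activation gave the lowest adjusted p of the 20 tested lists in this comparison (camera adjusted p = 3.06e-18; adjusted p = 0.214 with an estimated correlation). Of its 13 tested genes, 6 were higher, 2 lower and 5 not called, and 9 passed when adjusted over the list alone (7 higher, 2 lower). Beside Arg1 and Tgm2, the lectin genes Clec10a and Mgl2 rose by 2.36 ± 0.215 and 0.90 ± 0.072 log2 units. The PPAR list held 7 higher, 2 lower and 22 not called genes, and 11 passed when adjusted over the list alone (8 higher, 3 lower). Camera gave this list an adjusted p = 2.59e-06, and an adjusted p = 0.376 with an estimated correlation. Hilpda, Angptl4 and Cpt1a, genes of triglyceride storage and fatty acid import into mitochondria, rose by 1.73 ± 0.110, 1.06 ± 0.148 and 0.73 ± 0.062. Pdk4, another PPAR target, had 0 counts in every library. Among 12 tested RAR targets and retinoid genes, 2 were higher, 1 lower and 9 not called, with 4 passing when adjusted over the list alone (3 higher, 1 lower). For the list, camera's adjusted p = 1.33e-07 became an adjusted p = 0.329 with an estimated correlation. Dhrs3, a retinaldehyde reductase gene, rose by 0.72 ± 0.053. Cyp26a1, the RAR-driven retinoic acid hydroxylase, had 4, 0 and 0 counts with BEX against 19 untreated and was called lower (adjusted p = 0.0329), but not with offsets for GC content and gene length (adjusted p = 0.0713, range over the alternatives 0.00431 to 0.0713). Rarb had 0 counts in every library, and Cyp26b1 was too low to test.

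LXR targets moved both ways. Of 19 tested, 3 were higher (Abca1, Apoc2 by 0.97 ± 0.115, Mertk by 0.89 ± 0.075), 5 were lower and 11 were not called, with 9 passing when adjusted over the list alone (3 higher, 6 lower). Mylip, which encodes an LXR-induced ubiquitin ligase, fell by 0.44 ± 0.097 and Arl4c fell by 0.33 ± 0.054. Abcg1 stood at 204 ± 5.99 CPM against 224 untreated and was not called (log2 fold change -0.135 ± 0.060, adjusted p = 0.0885). It was called lower without BEX replicate 3 (log2 fold change -0.155, adjusted p = 0.036) and with GC and length offsets (adjusted p = 0.0366, range over the alternatives 0.036 to 0.191). Apoe was not called (log2 fold change 0.013 ± 0.066). The LXR median was -0.06 while its mean (0.167) and its test pointed up (camera adjusted p = 0.498).

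Fatty acid and triglyceride synthesis had 11 higher, 2 lower and 9 not called genes, with 15 passing when adjusted over the list alone (12 higher, 3 lower). As a list it had a camera adjusted p = 0.000981, and an adjusted p = 0.402 with an estimated correlation. Acaca, which makes malonyl-CoA, rose from 107 to 201 ± 12.8 CPM. Acsl3 rose by 0.43 ± 0.071 and Lpcat3 by 0.49 ± 0.070, whereas Srebf1, the LXR-driven regulator of this pathway, fell by 0.28 ± 0.068. Scd2 was called higher (log2 fold change 0.145, adjusted p = 0.0315). It was not called without BEX replicate 1 (0.149, adjusted p = 0.0734) or with the offsets (adjusted p = 0.145, range 0.00637 to 0.145). Cholesterol synthesis and uptake had 7 higher, 0 lower and 18 not called genes, 8 passing when adjusted over the list alone (7 higher, 1 lower). The list's camera adjusted p = 0.0349 stood beside an adjusted p = 0.376 with an estimated correlation. Sc5d and Insig1 rose by 0.40 ± 0.069 and 0.30 ± 0.063.

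The unfolded protein and integrated stress response list rose, with 10 higher, 2 lower and 17 not called genes, 16 passing when adjusted over the list alone (14 higher, 2 lower). Camera gave this list an adjusted p = 0.00325, and an adjusted p = 0.376 with an estimated correlation. Its lead genes were ATF4-linked: Sesn2 rose by 0.84 ± 0.101, Trib3 by 0.63 ± 0.082, Slc7a5 by 0.59 ± 0.073 and Atf4 itself by 0.45 ± 0.056. Cell cycle genes fell, with 0 higher, 14 lower and 19 not called, 15 passing when adjusted over the list alone (0 higher, 15 lower). For the list, camera's adjusted p = 5.91e-06 became an adjusted p = 0.306 with an estimated correlation. The replication licensing genes Cdc6, Cdt1 and Mcm5 fell by 0.65 ± 0.097, 0.64 ± 0.081 and 0.39 ± 0.068. Efferocytosis and phagocytic receptors counted 10 higher, 6 lower and 14 not called, 17 passing when adjusted over the list alone (10 higher, 7 lower). C5ar1 and Treml2 rose by 0.98 ± 0.051 and 1.41 ± 0.085, whereas Itgb3 fell by 1.36 ± 0.097. The efferocytosis call (camera adjusted p = 0.0399; adjusted p = 0.376 with an estimated correlation) was lost without BEX replicate 2 (adjusted p = 0.148) and without BEX replicate 3 (adjusted p = 0.1).

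Inflammatory genes moved both ways under BEX: 6 were higher, 9 lower and 19 not called, 21 passing when adjusted over the list alone (8 higher, 13 lower), and the list was not called (camera adjusted p = 0.684, median -0.084, mean 0.012). The neutrophil chemokine gene Cxcl2 rose 3.62-fold to 147 ± 3.60 CPM, and Tlr4 and Ccl2 rose by 0.79 ± 0.053 and 0.55 ± 0.046. Tnf, the classic macrophage cytokine, fell by 0.78 ± 0.082. Il1b was called lower (log2 fold change -0.45 ± 0.128, adjusted p = 0.0283), though not without BEX replicate 1 (adjusted p = 0.0608) or with DESeq2 (adjusted p = 0.167, range 0.00902 to 0.167). Interferon-stimulated genes counted 4 higher, 0 lower and 25 not called, 4 passing when adjusted over the list alone (4 higher, 0 lower), led by Rsad2 (0.56 ± 0.125) and Oasl1 (0.39 ± 0.083). That list was not called (camera adjusted p = 0.0891), but it was called higher without BEX replicate 2 (adjusted p = 1.15e-05) and with the offsets (adjusted p = 0.0487).

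Microglial state lists leaned down without reaching the threshold. Disease-associated microglia genes counted 3 higher, 13 lower and 14 not called, 19 passing when adjusted over the list alone (4 higher, 15 lower, camera adjusted p = 0.129, and 0.0034 without BEX replicate 2). Ccl6 was its strongest rise, from 701 to 2176 ± 24.3 CPM, and Lilrb4a fell by 0.50 ± 0.049. Homeostatic microglia genes counted 3 higher, 7 lower and 9 not called, 12 passing when adjusted over the list alone (3 higher, 9 lower, camera adjusted p = 0.129). Olfml3 fell by 0.64 ± 0.102 and Selplg by 0.34 ± 0.061. Among amyloid handling and processing genes, 8 were higher, 5 lower and 15 not called, 15 passing when adjusted over the list alone (9 higher, 6 lower, camera adjusted p = 0.281). The alpha-secretase gene Adam10 and Picalm rose by 0.68 ± 0.056 and 0.62 ± 0.055, and Cd33, which restrains microglial uptake, fell by 0.79 ± 0.069. NRF2 targets (2 higher, 6 lower, 16 not called, with 8 adjusted over the list alone as 2 higher and 6 lower, camera adjusted p = 0.223) and immediate-early genes (1 higher, 5 lower, 11 not called, with 8 adjusted over the list alone as 2 higher and 6 lower, camera adjusted p = 0.223) were not called as lists. Osgin1 rose by 1.15 ± 0.116 and Jun fell by 0.45 ± 0.064. RXR and its partners (3 higher, 0 lower, 16 not called, with 4 adjusted over the list alone as 3 higher and 1 lower, median -0.051 and mean -0.049 against a test pointing up, camera adjusted p = 0.675) included Ncoa3, up by 0.40 ± 0.060, and Rxra, which was not called. None of the 13 mitochondrially encoded genes was called by edgeR, and 0 passed when adjusted over the list alone (median 0.001, mean 0.011, a test pointing down, camera adjusted p = 0.999).

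At the extremes of the BEX response stood genes with little or no signal in untreated cells. Camkk1, a calcium-dependent kinase gene (Entrez gene 55984, chromosome 11, 73016043 to 73042073), rose from 0.197 to 8.12 ± 0.256 CPM, and Pram1 rose from 1.15 to 15.7 ± 2.27 CPM. Against the floor of 3 counts in the untreated library, Bach2 was at least 22.3-fold higher, Fam20a at least 14.5-fold and Tubg2 at least 12.8-fold. Bglap3 was at least 15.8-fold higher, but it has the near-copy Bglap2, so its assignment is uncertain. Npcd, also without a count in the untreated library, shares its strand and position with Nptxr and Cbx6, and the split of reads between them is uncertain. Named falls included Tymp, Ptchd1, St8sia1 and Areg, at log2 fold changes of -2.54, -1.79, -1.77 and -1.54, and Tymp overlaps Sco2. Rn7s1 and Rn7s2 ranked between Tymp and Ptchd1, at -2.25 and -2.15, and stood at -2.555 each with 6OHA. Each had 152 counts in the untreated library against 19 to 54 in the treated libraries. A deviation of the lone untreated library cannot be told apart from a response to both agonists there. The same holds for Bach2, Fam20a and Tubg2, which had 0 counts in that library and counts in every treated library.

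6OHA raised Plin2, Vegfa, Abca1 and Abcg1. Plin2 reached 1759 CPM, a log2 fold change of 2.04 ± 0.053 (adjusted p = 2.31e-11), and Vegfa, the vascular growth factor gene (Entrez gene 22339, chromosome 17, 46016993 to 46032377), rose 6.38-fold from 19.1 to 122 CPM. Abca1 rose 3.56-fold from 400 to 1424 CPM (adjusted p = 4.92e-10). Abcg1, its partner in cholesterol export to HDL (Entrez gene 11307, chromosome 17, 31057694 to 31117984), rose from 224 to 442 CPM, or by 0.98 ± 0.072 (adjusted p = 4.69e-07). Across tested genes 1173 were higher and 1112 lower (51.3% higher, against 62.2% with limma on log2(TPM + 1)), and 169 of the 2285 changed at least 2-fold. With GC and length offsets 1341 genes were called. Here 1 library was compared with 1, so the contrast has no replicate check of its own.

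LXR targets rose as a list under 6OHA, with 6 higher, 1 lower and 12 not called genes, 11 passing when adjusted over the list alone (7 higher, 4 lower). As a list it had a camera adjusted p = 1.8e-07, and an adjusted p = 0.222 with an estimated correlation. Mylip rose by 0.61 ± 0.111, Mertk by 0.89 ± 0.090 and Apoc2 by 0.855 ± 0.136. Fatty acid and triglyceride synthesis rose, with 9 higher, 1 lower and 12 not called genes, 11 passing when adjusted over the list alone (10 higher, 1 lower). The list's camera adjusted p = 1.17e-09 stood beside an adjusted p = 0.222 with an estimated correlation. Acaca rose by 1.32 ± 0.097, Acsl3 by 0.81 ± 0.085, Scd2 by 0.75 ± 0.062 and Fasn by 0.39 ± 0.075. Srebf1 was not called (0.097 ± 0.082, adjusted p = 0.389), although it was called higher with the offsets (0.279, adjusted p = 0.0129, range 0.0129 to 0.481). Cholesterol synthesis and uptake also rose, with 12 higher, 0 lower and 13 not called genes, 17 passing when adjusted over the list alone (16 higher, 1 lower). Camera gave this list an adjusted p = 5.95e-07, and an adjusted p = 0.222 with an estimated correlation. Lss and Sc5d rose by 0.66 ± 0.108 and 0.475 ± 0.083. PPAR targets (7 higher, 1 lower, 23 not called, with 8 adjusted over the list alone as 7 higher and 1 lower) had a camera adjusted p = 5.95e-07 and an adjusted p = 0.222 with an estimated correlation, and Hilpda, Angptl4 and Cpt1a rose by 1.41 ± 0.128, 1.22 ± 0.169 and 0.95 ± 0.075.

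Alternative activation genes rose under 6OHA, with 6 higher, 2 lower and 5 not called, 9 passing when adjusted over the list alone (7 higher, 2 lower). For the list, camera's adjusted p = 6.66e-08 became an adjusted p = 0.222 with an estimated correlation. Arg1 reached 11.8 CPM, a 4.23-fold rise, Tgm2 rose 2.55-fold to 726 CPM and Clec10a rose by 1.71 ± 0.241. RAR targets counted 3 higher, 0 lower and 9 not called, 4 passing when adjusted over the list alone (3 higher, 1 lower), among them Dhrs3 (0.31 ± 0.065) and Rdh11 (0.36 ± 0.101). The RAR list was called upward (camera adjusted p = 0.00118; adjusted p = 0.34 with an estimated correlation, median 0.149, mean -0.376 including Cyp26a1 at 0 counts), but not without BEX replicate 2 (adjusted p = 0.0569).

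Interferon-stimulated genes fell under 6OHA: 0 were higher, 12 lower and 17 not called, 21 passing when adjusted over the list alone (0 higher, 21 lower). As a list it had a camera adjusted p = 2.92e-08, and an adjusted p = 0.423 with an estimated correlation. The list's estimated correlation was 0.854 against the preset 0.01, and fry did not call the list. Ifit3, an interferon-induced antiviral gene (Entrez gene 15959, chromosome 19, 34583119 to 34588982), fell from 54.8 to 31.6 CPM, by 0.80 ± 0.171 on the log2 scale, and Stat2 and Oas3 fell by 0.34 ± 0.083 and 0.35 ± 0.077. Bst2 was called lower (log2 fold change -0.44), but not with the offsets (-0.271, adjusted p = 0.127, range 3.39e-06 to 0.127). Inflammatory genes counted 5 higher, 11 lower and 18 not called, 17 passing when adjusted over the list alone (5 higher, 12 lower, camera adjusted p = 0.284, and 0.0495 without BEX replicate 2). Il1a, Cxcl2 and Ccl2 rose by 1.35 ± 0.107, 1.04 ± 0.089 and 0.60 ± 0.056, and Tnf and Cd14 fell by 0.53 ± 0.101 and 0.515 ± 0.055. Cell cycle genes counted 1 higher (Mki67, by 0.29 ± 0.069), 13 lower and 19 not called, 18 passing when adjusted over the list alone (3 higher, 15 lower, camera adjusted p = 0.000331, and adjusted p = 0.222 with an estimated correlation), with Cdt1 down from 68.6 to 37.1 CPM. Mitochondrially encoded genes counted 5 higher, 0 lower and 8 not called, 7 passing when adjusted over the list alone (7 higher, 0 lower, camera adjusted p = 0.00649, and adjusted p = 0.423 with an estimated correlation), with ND5 up by 0.25 ± 0.063. NRF2 targets fell (1 higher, 3 lower, 20 not called, with 10 adjusted over the list alone as 2 higher and 8 lower, camera adjusted p = 0.0232, and adjusted p = 0.423 with an estimated correlation), with the iron store gene Ftl1, which has near-copies, down from 11210 to 6573 CPM.

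Lists that were not called under 6OHA still held single changed genes. Trem2, the lipid-sensing microglial receptor gene, fell from 348 to 287 CPM (by 0.28 ± 0.071) in the disease-associated list (4 higher, 7 lower, 19 not called, with 17 adjusted over the list alone as 4 higher and 13 lower, camera adjusted p = 0.284, and 0.0485 without BEX replicate 2), where Axl and Ctsd rose by 0.47 ± 0.065 and 0.34 ± 0.043. Homeostatic genes (1 higher, 7 lower, 11 not called, with 9 adjusted over the list alone as 2 higher and 7 lower, camera adjusted p = 0.0753) included Cx3cr1 and Selplg, down by 0.52 ± 0.117 and 0.43 ± 0.075. Amyloid genes (6 higher, 2 lower, 20 not called, with 11 adjusted over the list alone as 6 higher and 5 lower, median -0.025 and mean -0.006 against a test pointing up, camera adjusted p = 0.284) included Adam10, up by 0.60 ± 0.068. Efferocytosis genes (8 higher, 6 lower, 16 not called, with 17 adjusted over the list alone as 9 higher and 8 lower, camera adjusted p = 0.132) were called as a list with the offsets (adjusted p = 0.00521). The stress response list (1 higher, 5 lower, 23 not called, with 6 adjusted over the list alone as 1 higher and 5 lower, camera adjusted p = 0.233) held Slc3a2, down by 0.39 ± 0.070, and immediate-early genes (0 higher, 4 lower, 13 not called, with 4 adjusted over the list alone as 0 higher and 4 lower, camera adjusted p = 0.0657) held Jun, down by 0.645 ± 0.080. RXR and its partners (2 higher, 2 lower, 15 not called, with 6 adjusted over the list alone as 2 higher and 4 lower, camera adjusted p = 0.571) included Nr1h2, the LXR beta gene, called lower (log2 fold change -0.62 ± 0.104) but not with the offsets (-0.304, adjusted p = 0.0518, range 6.25e-07 to 0.0518). Rxra was not called (-0.191 ± 0.075, adjusted p = 0.0554), and was called lower without BEX replicate 2 (-0.192, adjusted p = 0.0198) and without BEX replicate 3 (-0.192, adjusted p = 0.04, range 0.0198 to 0.523).

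Bach2 (at least 28.5-fold), Tubg2 (at least 11.7-fold) and Fam20a (at least 5.5-fold) were higher with 6OHA and had no count in the untreated library. For these genes a deviation of that lone library cannot be told apart from a response. Zfp369 rose from 4.02 to 27.0 CPM, or by 2.75 ± 0.197. Bach2 overlaps the antisense gene Bach2os. Among falls, Clcn2 and Eva1c had 0 counts with 6OHA and were at least 7.12-fold and 6.15-fold lower than untreated. Both had counts in every other library, so a deviation of the lone 6OHA library cannot be told apart from a response. LOC115488487 was at least 21.7-fold lower but overlaps Cyth4, so that value is uncertain.

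**Figure D1:**
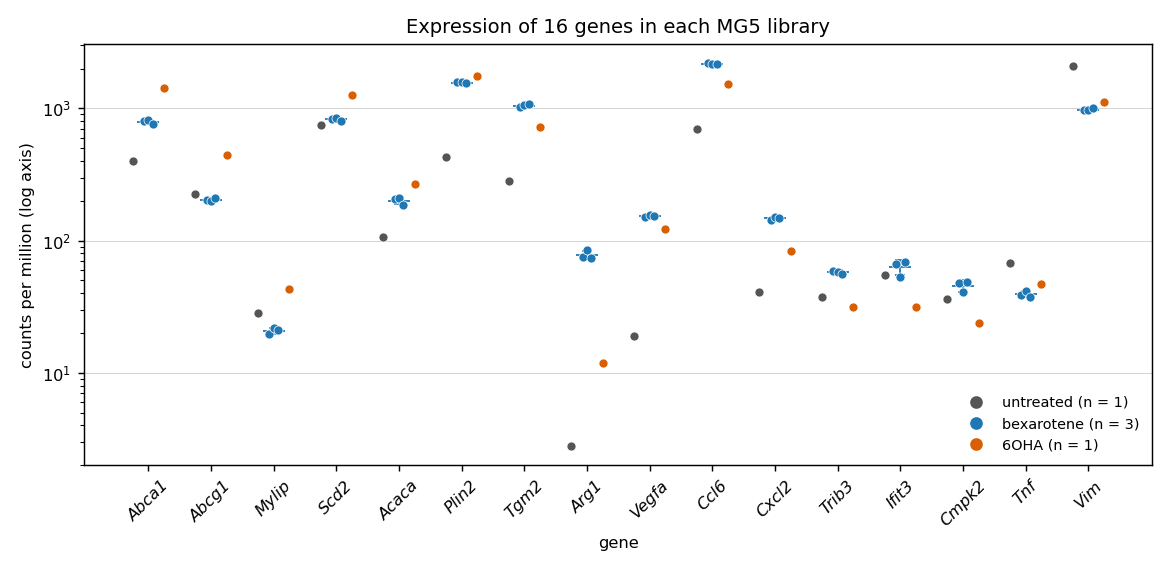
Levels of 16 genes in each of the 5 libraries, in CPM on a log axis: dots are libraries, coloured by group, and bars are the BEX mean ± SD (n = 3). Abca1 stood at 1424 CPM with 6OHA against 793 with BEX and 400 untreated, while Arg1 stood at 11.8, 77.7 and 2.78 CPM.

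At the same dose and time, Abcg1, Abca1 and Mylip were higher with 6OHA than with BEX, and Arg1 was lower. Abcg1 was 442 CPM with 6OHA and 204 ± 5.99 with BEX, a log2 difference of 1.115 (95% interval 0.99 to 1.24, adjusted p = 4.52e-08). Abca1 was higher by 0.845 (0.73 to 0.96, adjusted p = 1.4e-07) and Mylip (Entrez gene 218203, chromosome 13, 45389742 to 45411940) by 1.045 (0.85 to 1.24, adjusted p = 1.32e-05). Arg1 was 6.59-fold lower with 6OHA, a log2 difference of -2.72 (-3.01 to -2.43, adjusted p = 4.52e-08). Of 1010 genes called between the agonists, 371 were higher and 639 lower with 6OHA (36.7% higher, against 53.3% with GC and length offsets and 24.7% with limma on log2(TPM + 1)), and 56 differed at least 2-fold. Leaving out BEX replicate 2 raised the count to 1660.

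LXR targets were higher with 6OHA, at a median of 0.061 and a mean of 0.138 over the 19 tested (6 higher, 0 lower, 13 not called, with 7 adjusted over the list alone as 6 higher and 1 lower). The list's camera adjusted p = 1.13e-13 stood beside an adjusted p = 0.174 with an estimated correlation. Arl4c and Lpl were higher by 0.55 (0.44 to 0.67) and 0.40 (0.24 to 0.57). Mertk differed by 0.001 (-0.15 to 0.15) and Apoc2 differed by -0.11 (-0.33 to 0.11). Apoe was not called (-0.172, -0.315 to -0.029, adjusted p = 0.0733), but it was called lower with 6OHA without BEX replicate 1 (adjusted p = 0.0142), without BEX replicate 2 (adjusted p = 0.0243) and with DESeq2 (adjusted p = 0.0335, range 0.0142 to 0.912). Fatty acid synthesis genes were higher (8 higher, 0 lower, 14 not called, with 10 adjusted over the list alone as 8 higher and 2 lower, camera adjusted p = 1.33e-06, and adjusted p = 0.32 with an estimated correlation), with a median of 0.083 and a mean of -0.021. Scd2 was higher by 0.60 (0.495 to 0.71, adjusted p = 3.26e-06), Acaca by 0.41 (0.245 to 0.58), Scd1 by 0.39 (0.25 to 0.53) and Srebf1 by 0.38 (0.23 to 0.52). Fasn was called higher by 0.18 (0.046 to 0.31, adjusted p = 0.0442), but not without BEX replicate 1 (0.16, adjusted p = 0.11) or with limma-voom (adjusted p = 0.063, range 0.000147 to 0.11). Cholesterol synthesis genes were higher (7 higher, 0 lower, 18 not called, with 16 adjusted over the list alone as 14 higher and 2 lower, camera adjusted p = 7.9e-06, and adjusted p = 0.174 with an estimated correlation), with Lss at 0.38 (0.19 to 0.56) and Hmgcs1 at 0.25 (0.10 to 0.40).

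PPAR targets did not separate the agonists as a list (2 higher, 2 lower, 27 not called, with 4 adjusted over the list alone as 2 higher and 2 lower, median 0.001 and mean -0.073 against a test pointing up, camera adjusted p = 0.689). Plin2 was higher by 0.16 (0.072 to 0.26, adjusted p = 0.0118), Angptl4 was not called (0.16, -0.092 to 0.42) and Slc25a20 differed by 0.019 (-0.157 to 0.195). Cd36 was not called (0.13, 0.008 to 0.254, adjusted p = 0.106), but was called higher without BEX replicate 3 (0.153, adjusted p = 0.032, range 0.032 to 0.169). RAR targets were lower with 6OHA (0 higher, 2 lower, 10 not called, with 4 adjusted over the list alone as 1 higher and 3 lower, median -0.119, or -0.065 with genes at 0 counts set to their bound). Camera gave this list an adjusted p = 0.00255, and an adjusted p = 0.325 with an estimated correlation. Tgm2 and Dhrs3 were lower by log2 differences of -0.53 (-0.64 to -0.42) and -0.405 (-0.52 to -0.29). Alternative activation genes were lower (2 higher, 5 lower, 6 not called, with 9 adjusted over the list alone as 3 higher and 6 lower, camera adjusted p = 1.91e-07, and adjusted p = 0.174 with an estimated correlation), Clec10a by -0.65 (-0.95 to -0.35).

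Interferon-stimulated genes were lower with 6OHA than with BEX in 23 of 29 tested members, with 0 higher and 6 not called, and 26 passed when adjusted over the list alone (0 higher, 26 lower). For the list, camera's adjusted p = 1.83e-31 became an adjusted p = 0.325 with an estimated correlation. The list's members moved closely together, with an estimated correlation of 0.856 against the preset 0.01, so they are not independent of each other. Fry did not call the list. Ifit3, Cmpk2 and Stat2 differed by -0.99 (-1.30 to -0.68), -0.93 (-1.19 to -0.66) and -0.47 (-0.62 to -0.32). The stress response list was lower (0 higher, 10 lower, 19 not called, with 13 adjusted over the list alone as 1 higher and 12 lower). As a list it had a camera adjusted p = 5.62e-11, and an adjusted p = 0.174 with an estimated correlation. Trib3 (Entrez gene 228775, chromosome 2, 152337425 to 152344060) was 31.5 CPM with 6OHA and 57.7 ± 1.76 with BEX, a log2 difference of -0.87 (-1.06 to -0.69, adjusted p = 3.47e-05), and Atf4 differed by -0.46 (-0.585 to -0.34). Inflammatory genes as a list were lower (2 higher, 4 lower, 28 not called, with 8 adjusted over the list alone as 4 higher and 4 lower). The list's camera adjusted p = 0.00576 stood beside an adjusted p = 0.295 with an estimated correlation. Cxcl2 and Tlr4 differed by -0.82 (-0.965 to -0.67) and -0.44 (-0.55 to -0.32), whereas Ccl2 differed by 0.047 (-0.053 to 0.146) and Tnf was not called (0.25, 0.064 to 0.44, adjusted p = 0.0693). Tnf was called higher with 6OHA without BEX replicate 2 (0.291, adjusted p = 0.00714) and with the offsets (adjusted p = 0.0392, range 0.00714 to 0.153). Mitochondrially encoded genes were higher with 6OHA (4 higher, 0 lower, 9 not called, with 11 adjusted over the list alone as 11 higher and 0 lower, camera adjusted p = 6.93e-06, and adjusted p = 0.376 with an estimated correlation), ND5 by 0.24 (0.13 to 0.35).

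Microglial state lists differed between the agonists in single genes going both ways, with neither list called by camera. Homeostatic genes (2 higher, 3 lower, 14 not called, with 8 adjusted over the list alone as 3 higher and 5 lower, median 0.010 and mean 0.021 against a test pointing down, camera adjusted p = 0.689) included Cx3cr1 at -0.50 (-0.71 to -0.29) and P2ry13 at 0.43 (0.26 to 0.595). Disease-associated genes (3 higher, 4 lower, 23 not called, with 11 adjusted over the list alone as 6 higher and 5 lower, median 0.025, mean -0.004, camera adjusted p = 0.701) included Trem2 at -0.192 (-0.32 to -0.066, adjusted p = 0.0298) and Ctsd at -0.025 (-0.101 to 0.051). Amyloid genes (4 higher, 2 lower, 22 not called, with 10 adjusted over the list alone as 6 higher and 4 lower, camera adjusted p = 0.926) included Adam10 at -0.083 (-0.20 to 0.037) and Picalm at -0.094 (-0.21 to 0.025). Efferocytosis (3 higher, 4 lower, 23 not called, with 7 adjusted over the list alone as 3 higher and 4 lower, camera adjusted p = 0.39) and cell cycle genes (2 higher, 1 lower, 30 not called, with 3 adjusted over the list alone as 2 higher and 1 lower, camera adjusted p = 0.545) were not called as lists. NRF2 targets (1 higher, 5 lower, 18 not called, with 8 adjusted over the list alone as 2 higher and 6 lower, camera adjusted p = 0.104) were called lower without BEX replicate 2 (adjusted p = 0.0452), and Osgin1 was lower by -0.57 (-0.805 to -0.34). Immediate-early genes (1 higher, 2 lower, 14 not called, with 5 adjusted over the list alone as 2 higher and 3 lower, median 0.011, mean -0.041, camera adjusted p = 0.32) and RXR partners (0 higher, 1 lower, 18 not called, with 2 adjusted over the list alone as 0 higher and 2 lower, camera adjusted p = 0.16) were not called. Nr1h2, the RXR partner called lower (-0.41, -0.60 to -0.22), was not called with the offsets (-0.189, adjusted p = 0.178, range 0.000541 to 0.178).

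Among the genes named in this contrast that were called and had counts in both groups, Camkk1 differed most, at 0.434 CPM with 6OHA against 8.12 ± 0.256 with BEX (log2 difference -4.21, -5.29 to -3.16). Eva1c and Clcn2 had 0 counts with 6OHA and were at least 9-fold and 8.28-fold lower than with BEX. Here too a deviation of the lone 6OHA library cannot be told apart from a response. Npcd and Bglap3 also had 0 counts with 6OHA, and the near-copy of Bglap3 leaves its bound of 15.3-fold uncertain. Npcd had 0, 126, 139, 272 and 0 counts in the 6OHA, BEX 1 to 3 and untreated libraries while its same-strand neighbour Nptxr had 213, 85, 138, 4 and 262, so higher counts for Npcd went with lower counts for Nptxr and no fold is given. On the higher side, Slc39a10, a zinc importer gene, stood out with 0.75 (0.555 to 0.945), falling with BEX and not called with 6OHA. Moap1 was called higher by 1.02 (0.45 to 1.59, adjusted p = 0.0373), but not with limma-voom (adjusted p = 0.0545) or the offsets (adjusted p = 0.0625, range 0.00374 to 0.0625). Rplp2-ps1 and Rps27rt, near-copies of ribosomal protein genes, also ranked among the largest rises, and reads from their parents cannot be separated from theirs.

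**Figure D2:**
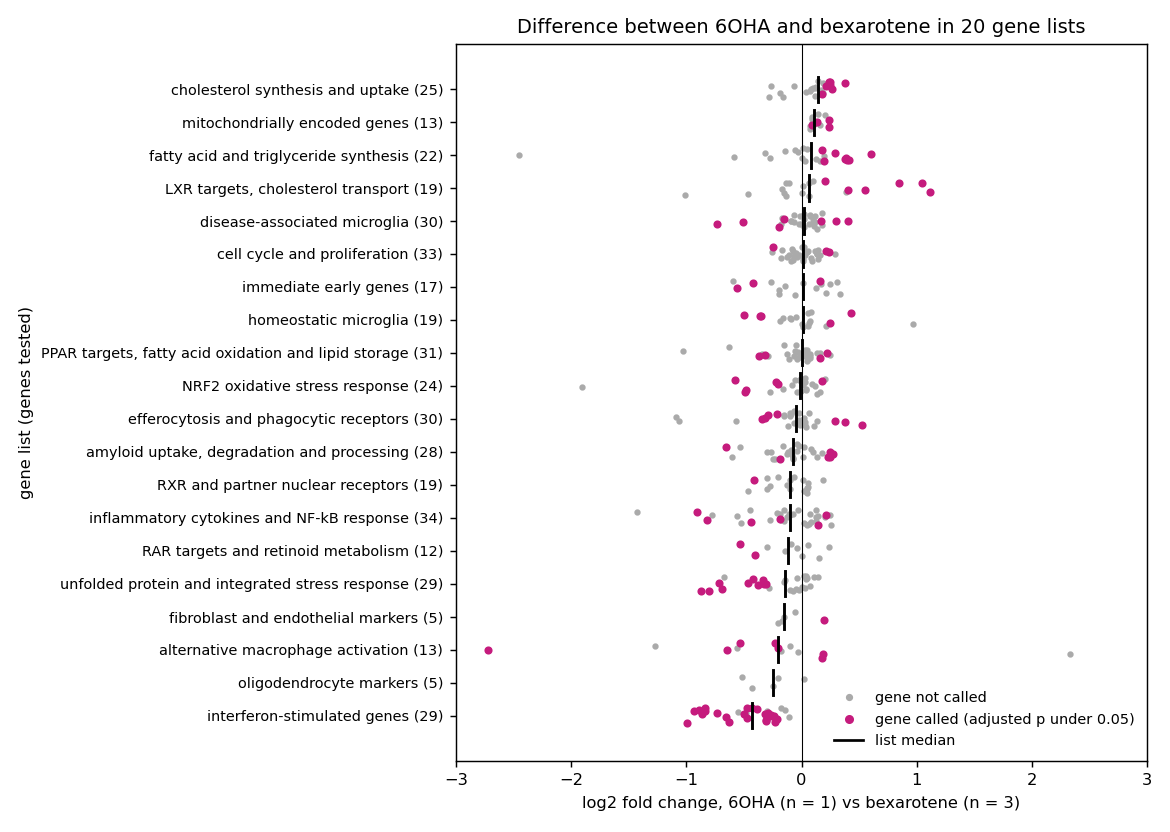
Log2 difference between 6OHA and BEX for each tested gene of the 20 tested lists: each point is a gene, black bars are list medians, and 3 genes lie past the axis limit of 3. The interferon-stimulated genes sit at a median of -0.427 and the cholesterol synthesis genes at 0.146.

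Vegfa, Plin2, Tgm2 and Mertk moved the same way under both agonists, which raises the question of how far the responses overlap. Of the 2101 genes called with BEX, 1980 (94.2%) had the same sign under 6OHA. Because both comparisons use the same single untreated library, groups simulated without any change gave 91.9% on average and 93.2% at most over 40 simulations, and the single control cannot be split. The covariance of the log2 fold changes across all tested genes was 0.537 against 0.163 (SD 0.0106) in the simulations, while the correlation across genes, which are not independent replicates, was 0.63 against 0.621. The simulated control varied only as much as a BEX library. A larger deviation of the real untreated library would raise the covariance too, so the simulations cannot tell it apart from a shared response. Genes at 0 in a group also weigh heavily in the covariance, such as Bach2 with fitted log2 fold changes of 9.10 and 9.44. All simulated groups took the BEX means, so genes counted only in the untreated library could not arise there. The gap in covariance therefore does not measure a shared response. Without each BEX library the sign share was 91.76% to 94.13%, lowest without BEX replicate 2, and no set was simulated with fewer BEX libraries. Calls shared in sign numbered 735 higher and 489 lower, counts that the shared control raises by an amount not measured here.

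Only 6 genes were called in opposite directions, and all of them were also called between the agonists: Mylip and Arl4c, lower with BEX and higher with 6OHA, and Cmpk2, Eif4ebp1, Thbs1 and Arid5a, higher with BEX and lower with 6OHA. The last 3 were chosen after their values were seen. Cmpk2 was not called with BEX under DESeq2 (adjusted p = 0.0544), limma-voom (adjusted p = 0.0679) or the offsets (adjusted p = 0.0594, range 9.42e-05 to 0.0679). Among genes called in all 3 comparisons with the same sign against untreated, 117 responded more to 6OHA and 95 more to BEX. Abca1 and Scd2 were in the former group and Arg1 and Tgm2 in the latter.

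**Figure D3:**
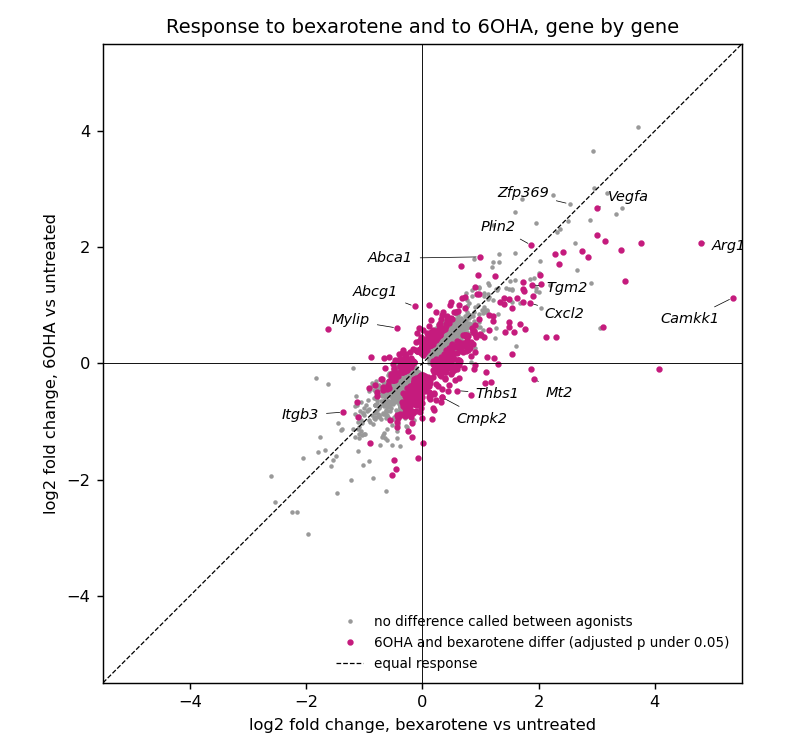
Log2 fold change with BEX (horizontal) against 6OHA (vertical), each relative to the same untreated library, for 3104 of the 3156 genes called in either comparison; 52 at 0 in a group or past the axes are left out. Magenta points are the 804 genes also called between the agonists, the dashed line marks equal change, and Abca1 (0.99 and 1.83) lies above it while Arg1 (4.80 and 2.08) lies below.

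Astrocyte and neuron transcripts were scarce, which matters because the medium came from astrocyte-like cells. Summed over each marker list, astrocyte genes reached 16.02 to 24.12 CPM per library (led by Aldh1l1), neuron genes 17.5 to 25.2 CPM (led by Syp) and oligodendrocyte genes 116 to 133 CPM (led by Mbp). Fibroblast and endothelial genes reached 254 to 306 CPM (led by Kdr at 178 to 229), against 6886 to 7093 CPM for homeostatic microglia genes. The astrocyte, neuron and fibroblast and endothelial sums were highest in the single untreated library, at 24.12, 25.16 and 306.4 CPM, against at most 20.51, 19.17 and 277.4 CPM in the treated libraries. Csf1r, the receptor gene that marks microglia and macrophages, stood at 2893 to 3032 CPM in the 5 libraries and differed by 0.010 (-0.080 to 0.101) between the agonists. Of 3 tested astrocyte genes, 1 was called lower with each agonist, Slc1a2 (log2 fold changes -1.09 and -1.22), and 0 between them. Of 4 neuron genes, Snap25 and Map2 were called lower with BEX, 0 with 6OHA and 0 between agonists. With DESeq2 neither was called (adjusted p = 0.187, range 0.0108 to 0.187, and adjusted p = 0.218, range 0.0129 to 0.218), and Map2 was not called without BEX replicate 1 (-0.50, adjusted p = 0.0582). Among 5 oligodendrocyte genes, Mbp rose with each agonist (0.29 and 0.31) and Mag was called lower with 6OHA, though not with DESeq2 (adjusted p = 0.0571) or the offsets (adjusted p = 0.0885, range 0.00189 to 0.0885). That list was not called (camera adjusted p = 0.935, 0.571 and 0.39 in BEX vs untreated, 6OHA vs untreated and 6OHA vs BEX, with a BEX median -0.011 and mean of -0.027 against a test pointing up). Fibroblast and endothelial genes were not called as a list (camera adjusted p = 0.177, 0.237 and 0.902, medians -0.125 and -0.248 against untreated, and median -0.155 and mean -0.077 between the agonists against a test pointing up). With fry that list was called lower with BEX (adjusted p = 0.0169) and with 6OHA (adjusted p = 0.0246). Kdr fell with BEX (by 0.35) and was higher with 6OHA than with BEX by 0.20 (0.070 to 0.32), a difference not called without BEX replicate 1 (0.197, adjusted p = 0.0565, range 0.00412 to 0.0565).

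Several named genes share their position with another gene, and how the counting used strand was not given in the sources used here. Srebf1 overlaps Rai1, Lpcat3 overlaps Emg1, Acaca overlaps Tada2a, Dhrs3 overlaps Vps13d, Ccl6 overlaps E230016K23Rik, Il1a overlaps Gm14023 and P2ry13 overlaps Med12l, all on the opposite strand. Plin2 overlaps LOC101055843 and Acsl3 overlaps Utp14b, both on the same strand. Arg1 overlaps Gm40616 and Osgin1 overlaps Gm32006. Part of the values of Plin2, Acsl3, Arg1 and Osgin1 can therefore belong to the neighbour.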

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

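The comparison of the 6OHA library with BEX library 2 alone and the share of genes with a stronger response were tests chosen after the results were seen, as were the offsets for GC content and length themselves. A list was picked when its camera test pointed in opposite directions under the agonists, called or not, and the difference between agonists was itself called. A named gene was picked when edgeR called it in opposite directions under the agonists and called the difference. Ribosomal protein genes and LXR targets, weighed further on, did not meet these rules and were added after their values were seen. The lists picked had median log2 differences (6OHA minus BEX) of -0.427 for interferon-stimulated genes, -0.103 for inflammatory genes, -0.14 for the stress response and 0.106 for mitochondrially encoded genes. The genes were Cmpk2 (-0.929), Mylip (1.045) and Arl4c (0.554). For the inflammatory, stress response and mitochondrial lists, no explanation was tested.

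Interferon-stimulated genes, Cmpk2 among them, were lower with 6OHA than with every BEX library in 29 of 29 tested members. After offsets for GC content and length the median was -0.432, and 20 members were called lower, which argues against a composition trend as the whole cause. BEX library 2 was itself below the other BEX libraries in 28 of 29 members, and the only 6OHA library carries the same number, so a shared batch was considered. The 6OHA library still had a median log2 ratio of -0.258 to BEX library 2, beside -0.477 to the other BEX libraries, but this sets 1 library against 1, and the list median varied between BEX libraries with an SD of 0.117. A shared batch, a difference between agonists and a chance difference between cultures therefore cannot be told apart, since only 1 6OHA library was used here.

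Ribosomal protein genes were lower in the 6OHA library than in the untreated library for 36 of 84 tested members by edgeR's call, with 0 called higher and a median of -0.146. With BEX, against the same untreated library, 10 were called lower at a median of -0.0831 (-0.018 after the offsets). Between agonists 21 were lower with 6OHA, at a median of -0.0569 (-0.049 after the offsets). GC content and length explained 11.5% of the variance of the 6OHA library's deviations, against 0.725% to 1.73% in BEX libraries and 5.11% in the untreated library. After the offsets the median was -0.0588 and 16 members were called lower, between the bounds set for a trend and for its absence. A composition trend of the 6OHA library, a level particular to the lone untreated library and a lower transcript level cannot be told apart for these genes, because both agonists share that control and the offsets can also remove a change shared by genes of similar length and GC content.

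LXR target genes, with Mylip and Arl4c in opposite directions, had 6 members called higher with 6OHA than with BEX, at a median of 0.699, while the median over all 19 tested members was 0.061. Those 6 were picked by their call in this same contrast, so their median was high by selection. For those 6, after the offsets the median was 0.685, and 7 of the list's members were called higher. The fitted GC and length trend thus accounts for little of the difference in those 6. No median after the offsets was taken over all 19, so the list as a whole was not tested this way. If 6OHA gave a stronger copy of the whole BEX response, nearly every shared gene that differs would respond more to 6OHA. The share was 55.2% of 212 genes, which argues against that for calls made without the offsets. It was not taken again with the offsets, so how far a GC and length trend enters it is unknown. A selective difference between the agonists on some LXR targets is a hypothesis these values leave open, and so is a difference between single cultures, which the libraries used here cannot test.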

How the results depend on the processing

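The offsets for GC content and length, the restriction to genes above 0 in every library and limma-voom for single genes were chosen after seeing the data, unlike all other settings. In BEX vs untreated, 2101 genes were called, and the count was 201 at an absolute log2 fold change of at least 1, 1216 with no filter, 908 with limma on log2(TPM + 1) and 975 on log2(TPM + 0.1), and 1841 to 2814 when each BEX library was left out. In 6OHA vs untreated, 2285 were called, against 169, 1134, 785 and 869 in the same order, 1341 with the offsets and 2287 to 3226 without each BEX library. In 6OHA vs BEX, 1010 were called, against 56, 190, 85 and 144 in that order and 867 to 1660 without each BEX library (1660 without BEX replicate 2). A fold minimum lowers a count by construction, and the cause was not tested for the other settings. RLE factors (2138, 2325 and 1027), DESeq2 (1475, 1651 and 770), limma-voom (1891, 2030 and 765), the older quasi-likelihood method (2086, 2329 and 1015), a minimum mean of 20 counts (2299, 2555 and 1206) and genes above 0 in every library (2305, 2543 and 1216) stayed within 1.5 times. The offsets gave 1856 and 801 in the contrasts with BEX. Fits of only 2 groups gave 2119 and 1068 in those contrasts. Calls shared with the reported ones all had the same sign, for example 1602, 1092 and 593 with the offsets and 1461, 1624 and 729 with DESeq2.

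Gene lists called numbered 8, 10 and 9, while with an estimated correlation 0, 0 and 0 passed, and with fry 7, 6 and 0. Without each BEX library the lists called were 7 to 9, 10 to 11 and 9 to 10. The share of BEX-called genes with the same sign under 6OHA was 94.2%, and 91.76% to 94.13% without each BEX library.

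Among named genes, Cebpb (0.099) and Junb (0.095) changed sign in 6OHA vs untreated with the offsets and were no longer called, and the cause was not tested. The offsets ended calls of 7, 10 and 14 other named genes in the 3 contrasts and left 95, 90 and 78 on their side of the threshold, and RLE factors left all 103, 103 and 93 there. No paired analysis was possible because BEX shares only number 3 with the untreated library and only number 2 with the 6OHA library, so a block for number leaves no residual degrees of freedom. Depth limited genes near the floor: with 0 counts in a library, levels below 0.0743 to 0.0885 CPM could not be seen.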

Other observations

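The tests of gene families and the genes named here were chosen after their values were seen. Families were picked by the start of the gene symbol, so they also count some genes that are not subunits. Tubgcp2 is counted with the tubulins, Psmg3 with the proteasome subunits, Ndufaf7 with the complex I genes and Atp6v0c-ps2 with the V-ATPase subunits. Mt1 and Mt2, the zinc-binding metallothionein genes, rose with BEX by 1.10 ± 0.080 and 1.93 ± 0.157 log2 units (SE) and were not called with 6OHA (-0.14 and -0.27). Between the agonists Mt1 differed by -1.24 (95% interval -1.41 to -1.06; adjusted p = 1.1e-06) and Mt2 by -2.20 (-2.57 to -1.83; adjusted p = 3.26e-06). Slc39a10, which imports zinc, fell with BEX by 0.66 and was not called with 6OHA (0.087). Among aminoacyl-tRNA synthetase genes, many of which ATF4 drives, 13 of 18 were higher with BEX and 0 lower (median 0.299; camera adjusted p = 6.9e-10; adjusted p = 0.473 with an estimated correlation), and with 6OHA 4 were higher and 1 lower. Between agonists 7 were lower with 6OHA and 0 higher (median -0.165; camera adjusted p = 2.62e-09; adjusted p = 0.527 with an estimated correlation). Wars led them, at 80.7 CPM with 6OHA and 120.0 ± 3.01 with BEX, against 77.7 untreated.

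Vim, the intermediate filament gene, fell from 2107 to 978 ± 18.9 CPM with BEX and to 1109 CPM with 6OHA. Ch25h, which makes the LXR ligand 25-hydroxycholesterol, fell by 0.905 ± 0.061 with BEX and by 1.37 ± 0.077 with 6OHA, and differed by -0.46 (-0.60 to -0.32; adjusted p = 0.000418) between them. Vegfa rose from 19.1 CPM to 153 ± 2.74 with BEX and 122 with 6OHA, and was lower with 6OHA by a log2 difference of -0.33 (-0.46 to -0.19; adjusted p = 0.00322). MHC genes counted 6 lower with BEX and 12 lower with 6OHA of 28 tested, with 0 higher in both. The 6OHA median was -0.247 (camera adjusted p = 5.39e-05; adjusted p = 0.561 with an estimated correlation) and -0.145 after the offsets for GC content and length. Nuclear complex I genes fell in 12 of 49 with 6OHA (median -0.181, and -0.129 after the offsets) and in 1 of 49 with BEX (median -0.095, and -0.045 after the offsets). Between the agonists 2 of 49 were called lower with 6OHA and 0 higher (median -0.134). Camera called this family in each contrast at the preset correlation and in none with an estimated correlation. The mitochondrially encoded genes of the same complex were higher or not called.

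V-ATPase subunits had 0 higher and 5 lower of 17 with BEX (median -0.102, camera adjusted p = 0.0184, and adjusted p = 0.473 with an estimated correlation). Also with BEX, tubulins counted 2 higher and 8 lower, and proteasome subunits 0 higher and 2 lower. With 6OHA V-ATPase subunits counted 1 higher and 3 lower, tubulins 2 and 3, and proteasome subunits 2 and 8. None of the 8 chaperonin TRiC genes was called by edgeR in the 3 contrasts.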
